A study of Caenorhabditis elegans with 24 samples.

How the data were processed

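Whole wild-type N2 (Bristol) Caenorhabditis elegans were measured on 24 Affymetrix arrays, 3 for each of 8 groups. Quercetin, a plant flavonol, was given at 0, 50, 100 and 200 µM, and tannic acid, a plant gallotannin, at 0, 100, 200 and 300 µM. Each compound had its own group of untreated controls. Per the labels' protocols, the parents were kept on the treatment plates for 4 days, eggs were isolated with hypochlorite, and the hatched animals grew on the same dose until harvest. The labels give the harvested animals as larvae of the fourth stage, whereas the growth protocol names young adults that had not begun to reproduce. The stage is therefore not settled here. Total RNA was amplified, labelled with biotin and hybridised.

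The deposited values were used as the authors gave them, on a log2 scale, 1 value per probe set and array. Per the submitters' processing notes the values were made with GCRMA, a method that corrects background by probe sequence, normalizes between arrays and summarises the probes of a set. Its version was not given in the sources used here. That the scale was log2 was read from the range of the values. The quercetin and tannic acid arrays lie on different scales. The array medians over all probe sets were 6.59 to 6.67 in the quercetin experiment and 3.72 to 3.95 in the tannic acid experiment. The standard deviations were 3.69 to 3.76 and 2.73 to 2.78. Levels were therefore never compared across the experiments, except in the contrast of the control groups. That contrast measures this offset together with any other difference between the experiments. Background correction of this kind spreads dim values far down the log2 scale, so that a large fold change of a dim probe set depends on the correction. The values also carry no call of presence.

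Of 22625 probe sets, the 77 AFFX control probe sets were left out. A probe set was kept when its log2 value was at least 4 on at least 3 of the 24 arrays, which left 14489. Gene symbols came from the platform annotation supplied with the series, which lists 21653 of the probe sets, 887 of them with several symbols. Among the probe sets kept, 13754 had 1 symbol, 494 had several and 241 had none. No gene was named from a probe set with several symbols. The probe sets kept with 1 symbol stand for 11057 genes, 2332 of which had several probe sets. In 3, 5 and 2 of these genes the probe sets were called in opposite directions at 50, 100 and 200 µM quercetin. The same held for 0, 0 and 22 genes at 100, 200 and 300 µM tannic acid. Probe sets with the suffix x_at or s_at, which can hybridise with transcripts of related genes, numbered 5704. No genome build was named in the sources used here, so no coordinates are printed.

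A group-means model was fitted to all 24 arrays with limma 3.58.1 in R 4.3.3, with 16 residual degrees of freedom and empirical Bayes moderation of the variance. Each dose was compared with the control group of the same compound. A linear trend over the 4 doses of each compound was tested as a slope per 100 µM. The difference between the responses to the compounds was tested at 100 and at 200 µM, and the control groups were compared with each other. All tests were two-sided, and a probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over the 14489 probe sets. Errors of fold changes are standard errors from this model, and errors of group means are standard deviations over 3 arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

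The 39 gene lists were written from gene names and textbook functions, with 1 probe set per gene, the one with the highest mean over all arrays. They were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists within a contrast. Camera with an estimated correlation and fry were run beside it. The counts of members called were also taken with the adjusted p computed over the list alone. Genes to be named were taken by a rule that required 1 symbol and a call. For each dose the rule took the 6 largest rises and the 6 largest falls in which the arrays of the groups did not overlap and the higher group had a mean of at least 6. It also took up to 4 called members of each list described, with the largest changes. It took for each compound the 8 genes with the largest mean change among those called in 1 direction at all doses. It further took the 10 genes with the largest mean change called in 1 direction for both compounds at 200 µM, the 5 most positive and 5 most negative differences at each matched dose, and the 4 steepest rises and falls of each trend. Groups, contrasts, lists, this rule and all alternatives except those named as added were fixed before the data were examined. The lists of dauer and male genes used in the closing section were added later.

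The labels do not say that the 3 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision. The correlation between arrays of a group was 0.997 to 0.999 in the quercetin experiment and 0.987 to 0.998 in the tannic acid experiment, and no arrays held identical values. The spread between arrays differed between the experiments. The median residual standard deviation was 0.112 for quercetin and 0.191 for tannic acid when each was fitted alone. A model shared by all arrays therefore takes too large a spread for quercetin and too small a spread for tannic acid.

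The procedure was tested on data simulated from the group means and the spreads of the arrays, with 200 of 14489 probe sets changed by a log2 difference of 0.5 or 1. At 50, 100 and 200 µM quercetin, 58%, 51% and 45% of the changes of 0.5 were recovered, and 96%, 93% and 95% of those of 1. The share of false calls was 4.3%, 5.3% and 4.1%. At 100, 200 and 300 µM tannic acid, 61%, 46% and 49% of the changes of 0.5 and 94%, 91% and 94% of those of 1 were recovered. There, 40.2%, 39.6% and 36.4% of the calls were false. With the tannic acid arrays fitted alone the false share was 8%, 4% and 8%, and 75%, 73% and 84% of the changes of 1 were recovered. The false share depends on how many probe sets change, and the simulated noise was independent. These shares therefore need not hold for the real counts. The fit over all arrays had been fixed beforehand and was kept, and the tannic acid counts are given beside those with the tannic acid arrays fitted alone. In a simulation of 39 lists of 20 genes, the 1 list shifted by 0.5 was called and 0 of the others were. Its noise was also independent between genes, so it cannot show how often camera calls lists whose genes vary together.

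Alternatives were no filter, a stricter filter at log2 6, median centring, quantile normalization of all arrays, each experiment alone, a variance trend with robust moderation, array weights, the replicate number as a block, 1 value per gene, a minimum change of 2-fold, and leaving out each array in turn. Raising values under log2 4 to 4, leaving out 4 tannic acid arrays and running camera on each experiment alone were added after the data had been seen. Counts limited to probe sets with a group above log2 4 in each experiment, the joint counts with each experiment fitted alone, and the check of same-numbered arrays among the treated groups were also added then.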

Results

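Expression was measured in whole C. elegans raised with quercetin or tannic acid, polyphenols made by plants, at 4 levels of dose each, including 0. The series asks how the transcriptome of wild-type animals differs between these doses. There were 3 arrays per group and 12 per experiment. Of all probe sets, 39.2% to 39.8% lay below log2 4 on the quercetin arrays and 50.3% to 52.5% on the tannic acid arrays. In all tannic acid groups 28 of 121 collagens, 23 of 70 C-type lectins, 20 of 59 lysozymes and antimicrobial peptides and 9 of 48 neuropeptide genes lay under log2 4, so a fall in these was not measurable. All p-values below are adjusted p from limma, and all fold changes are on the log2 scale with their standard error (SE) and 3 arrays per group. The number of probe sets called at each dose is shown in the bar plot of counts.

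**Figure D1:**
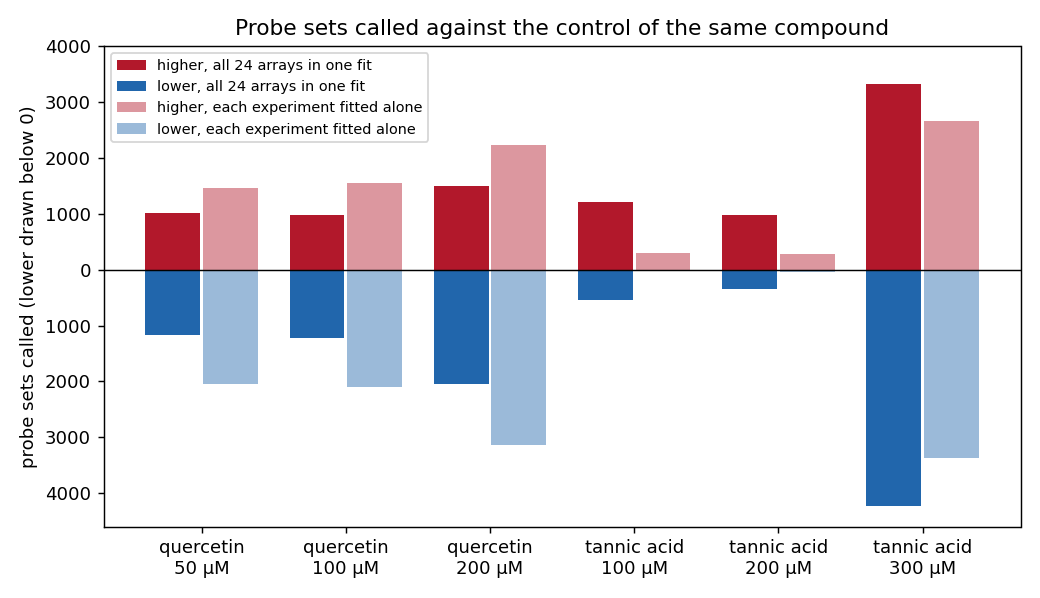
Number of probe sets called higher (above 0) and lower (below 0) than the control at each dose in µM, with limma on all 24 arrays and on each experiment alone. At 100 and 200 µM tannic acid the totals were 1747 and 1324 with all arrays and 323 and 316 with the tannic acid arrays alone.

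At 50 µM quercetin, the largest rises among the named genes were those of scl, grl and cuticlin genes. scl-13, which encodes a secreted protein of the SCP family, rose from 3.06 ± 0.25 to 10.72 ± 0.10 (SD, n = 3), a change of 7.66 ± 0.10 (SE; adjusted p = 1.9e-22). Its probe set carries the suffix s_at and can read related transcripts. The cuticlin gene cut-1 rose by 7.45 ± 0.15, and grl-25 and grl-20, of the ground-like family of hedgehog-related genes, rose by 7.38 ± 0.12 and 7.38 ± 0.16. scl-12 and scl-11 rose by 7.04 ± 0.07 and 6.48 ± 0.09. The controls of these genes lay near the bottom of the scale. With values under log2 4 raised to 4, the rises of scl-13, cut-1 and grl-20 were 6.72, 5.41 and 6.65. Among the genes that fell were the fasting-induced lipases fil-2 (-5.82 ± 0.14; adjusted p = 1.1e-17; -3.76 with low values raised in this way) and fil-1 (-3.78 ± 0.12) and the small heat shock genes hsp-16.41 (-3.44 ± 0.65; adjusted p = 0.00059) and hsp-16.2 (-2.31 ± 0.53). pud-4 fell by 1.99 ± 0.14.

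Sperm genes, a list of major sperm proteins and other genes of spermatogenesis, rose together at 50 µM quercetin. Of 62 members 47 rose and 0 fell, both over all genes and adjusted over the list alone, with a median of 1.77 (camera adjusted p = 1.2e-54, and adjusted p = 0.017 with an estimated correlation). ssp-34 rose by 3.36 ± 0.18 and gsp-3, a phosphatase of sperm, by 2.92 ± 0.16. Of 121 cuticle collagens 76 rose and 2 fell, or 85 and 4 adjusted over the list alone, with a median of 0.65 (adjusted p = 1.2e-41, and 0.0023 with an estimated correlation). Examples were col-158 at 6.45 ± 0.26, col-84 at 5.79 ± 0.15 and col-35 at 5.63 ± 0.13 (4.82 with low values raised). Of 86 genes of fatty acid metabolism 33 rose and 3 fell, or 37 and 3 adjusted over the list alone (median 0.22; adjusted p = 5e-10, and 0.017 with an estimated correlation). The fatty acid desaturases fat-5 and fat-7 rose by 5.35 ± 0.26 and 4.25 ± 0.36.

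Smaller groups also moved at this dose. Of 19 genes of the intracellular pathogen response 5 rose and 0 fell, also adjusted over the list alone, of which 3 had a group above log2 4, among them B0507.8 (2.45 ± 0.10), with adjusted p = 0.00074 and adjusted p = 0.16 with an estimated correlation. Of 59 lysozymes and antimicrobial peptides 15 rose and 8 fell, or 19 and 8 adjusted over the list alone, including spp-11, a saposin-like gene, at 4.49 ± 0.16 (4.03 with low values raised). Their adjusted p of 0.018 became adjusted p = 0.36 with an estimated correlation, and their median of 0.02 became 0.00 under quantile normalization. Of the 23 oocyte and eggshell genes limma called 0, with 0 at an unadjusted p under 0.05 and a median of -0.02 (camera adjusted p = 0.95, fry adjusted p = 0.9), and with the quercetin arrays alone 1 higher and 1 lower (1 and 3 unadjusted). In total 1007 probe sets were higher and 1169 lower. With the quercetin arrays fitted alone the count was 3496, of which 2049 were shared.

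At 100 µM quercetin, the secreted scl genes were again high, and lys-10, ilys-2 and targets of the p38 immune pathway fell. scl-13 rose by 7.46 ± 0.10 and scl-12 by 7.10 ± 0.07, and C23G10.11 and T26C12.2 rose by 6.51 ± 0.08 and 5.94 ± 0.13. With values under log2 4 raised to 4 the rises of scl-13, C23G10.11 and T26C12.2 were 6.52, 5.27 and 5.10. lys-10, a gene of the lysozyme family, fell from 13.66 ± 0.11 to 7.16 ± 0.17 (SD, n = 3), a change of -6.49 ± 0.10 (adjusted p = 6.4e-21). The invertebrate-type lysozyme ilys-2 fell by 3.80 ± 0.11, and F01D5.3 and W03F9.4 fell by 4.90 ± 0.23 and 4.89 ± 0.13. The list of 59 lysozymes and antimicrobial peptides as a whole had 17 higher and 10 lower, or 18 and 11 adjusted over the list alone (adjusted p = 0.072). fil-2 lay at -5.24 ± 0.14, or -3.76 with low values raised.

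Targets of the p38 immune pathway went down as a list at 100 µM quercetin. Of 17 members 11 fell and 1 rose, also adjusted over the list alone, with a median of -0.73 (adjusted p = 8.1e-07, and 0.044 with an estimated correlation). sysm-1 fell by 2.98 ± 0.15, lys-2 by 1.56 ± 0.08 and clec-85, a C-type lectin, by 1.52 ± 0.12. Of 70 C-type lectins 14 rose and 22 fell, or 16 and 24 adjusted over the list alone, with adjusted p = 0.41 for a common direction and a median of -0.03 that became 0.00 under median centring. Of the 19 pathogen response genes 8 rose and 1 fell, also adjusted over the list alone, pals-29 by 3.11 ± 0.24, or 0.89 with values under log2 4 raised to 4 (adjusted p = 1.5e-05, and adjusted p = 0.057 with an estimated correlation). Targets of the transcription factor DAF-16 that it activates were higher in 5 of 15 cases and lower in 0, also adjusted over the list alone, with hsp-12.6 at 2.21 ± 0.11 and the ferritin gene ftn-1 at 1.27 ± 0.16 (adjusted p = 0.011, and adjusted p = 0.057 with an estimated correlation).

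Sperm genes rose in 49 of 62 cases at this dose, also adjusted over the list alone, and none of the 62 fell (median 1.72; adjusted p = 3.2e-50, and 0.044 with an estimated correlation). Of the collagens 44 rose and 8 fell, or 49 and 8 adjusted over the list alone (median 0.24; adjusted p = 6.5e-11, and adjusted p = 0.095 with an estimated correlation). Of 10 hypoxia genes 4 fell and 0 rose, or 5 and 0 adjusted over the list alone, and 7 and 0 with the quercetin arrays alone, led by nhr-57 at -0.69 ± 0.15 (adjusted p = 0.016, and adjusted p = 0.057 with an estimated correlation). The yolk protein gene vit-1 fell by 1.61 ± 0.08 and was called with 0 of the other 4 vitellogenins. Adjusted over the list alone 2 of 5 were lower, and with the quercetin arrays alone 4. The superoxide dismutase gene sod-5 rose by 2.26 ± 0.10. In total 985 probe sets were higher and 1229 lower. Fitted alone, the quercetin arrays gave 3645, of which 2094 were shared.

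At 200 µM quercetin, scl genes were again highest, and more probe sets were called than at the lower doses. scl-13 rose from 3.06 ± 0.25 to 11.70 ± 0.10 (SD, n = 3), by 8.63 ± 0.10 (adjusted p = 1.8e-23), or by 7.70 with values under log2 4 raised to 4. scl-12, scl-11 and T26C12.2 rose by 7.95 ± 0.07, 7.46 ± 0.09 and 6.86 ± 0.13, and grl-20 and grl-25 by 6.28 ± 0.16 and 6.24 ± 0.12. For T26C12.2 and grl-20 the rises were 6.01 and 5.55 with low values raised. lys-10 fell by 6.92 ± 0.10 (adjusted p = 2.2e-21), the C-type lectin clec-190 by 5.06 ± 0.13, W03F9.4 by 4.99 ± 0.13 and ilys-2 by 4.08 ± 0.11. The cytochrome P450 gene cyp-33B1 rose by 5.05 ± 0.23, while 7 of 36 cytochrome P450 genes rose and 6 fell (adjusted p = 0.74).

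Sperm genes reached their highest median at 200 µM quercetin. Of 62 members 52 rose and 0 fell, also adjusted over the list alone, with a median of 2.18 (adjusted p = 1.4e-48, and adjusted p = 0.084 with an estimated correlation). ssp-34, gsp-3 and spe-18 rose by 4.10 ± 0.18, 3.72 ± 0.16 and 3.69 ± 0.23. Of the collagens 59 rose and 9 fell, or 62 and 9 adjusted over the list alone, including col-37 at 4.98 ± 0.15 and col-2 at 4.55 ± 0.10 (adjusted p = 3.6e-13, and adjusted p = 0.11 with an estimated correlation). Vitellogenins fell in 4 of 5 cases, also adjusted over the list alone, with vit-1 at -1.68 ± 0.08 and a median of -0.41 (adjusted p = 0.0052, and adjusted p = 0.29 with an estimated correlation). Of the oocyte list limma called 0 of 23, with 0 at an unadjusted p under 0.05 and a median of -0.10 (camera adjusted p = 0.37, fry adjusted p = 0.46). With the quercetin arrays alone it called 4 lower and 0 higher (5 and 0 unadjusted).

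Stress genes and some other lists moved in part at 200 µM quercetin. Of 13 oxidative stress targets of SKN-1 5 rose and 0 fell, or 6 and 0 adjusted over the list alone, among them gst-4 at 0.98 ± 0.25 (adjusted p = 0.032, and adjusted p = 0.34 with an estimated correlation). Of 25 antioxidant enzymes 4 rose and 0 fell, also adjusted over the list alone, and 9 and 1 with the quercetin arrays alone, led by sod-5 at 3.04 ± 0.10 and sod-3 at 1.02 ± 0.12 (adjusted p = 0.032, and adjusted p = 0.51 with an estimated correlation). Of 16 genes of the unfolded protein response of the endoplasmic reticulum 4 fell and 0 rose, or 6 and 0 adjusted over the list alone, and 11 and 0 with the quercetin arrays alone (adjusted p = 0.014, and adjusted p = 0.57 with an estimated correlation). Targets of the p38 pathway fell in 9 of 17 cases, also adjusted over the list alone, and 0 rose over all genes against 1 over the list, with sysm-1 at -3.41 ± 0.15 (adjusted p = 0.0025, and adjusted p = 0.2 with an estimated correlation). Neuropeptide genes were higher in 9 of 48 cases and lower in 1, or 6 and 1 adjusted over the list alone, and 22 and 1 with the quercetin arrays alone (adjusted p = 0.0053, and adjusted p = 0.29 with an estimated correlation). Of 22 neuronal markers, by contrast, 0 rose and 6 fell. In total 1488 probe sets were higher and 2054 lower. The quercetin arrays alone gave 5373, of which 3442 were shared.

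**Figure D2:**
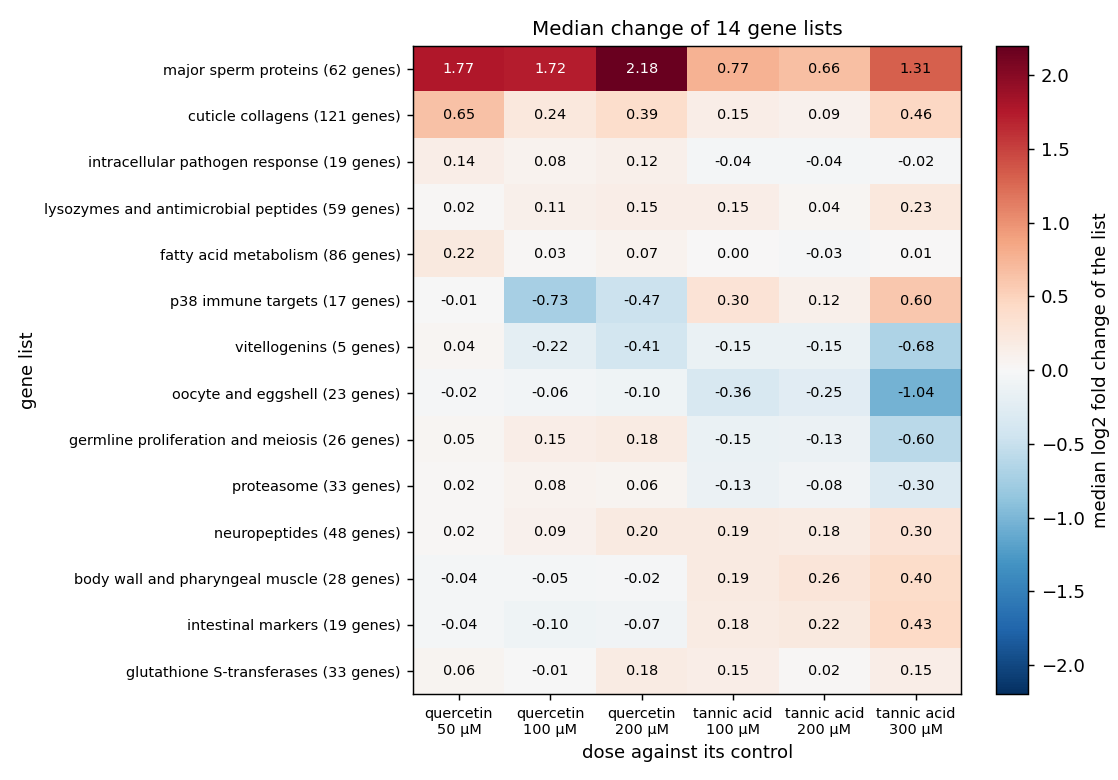
Median log2 fold change of 14 gene lists (vertical axis) at each dose against its control in µM (horizontal axis), with colour giving the median. The sperm list lay between 1.72 and 2.18 at the quercetin doses and between 0.66 and 1.31 at the tannic acid doses, and the oocyte list reached -1.04 at 300 µM tannic acid.

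Across the quercetin doses, 603 probe sets were called higher and 510 lower at all doses, and 800 and 894 with the quercetin arrays alone. Independent lists would share 7 and 14 with all arrays and 24 and 64 with the quercetin arrays alone. Simulations of unchanged groups against the same controls gave at most 0 and 0 in 20 draws. Unchanged groups give hardly any calls at a single dose, so these draws cannot measure what the shared controls add. Because 3 controls cannot be split with enough arrays in each part, part of the excess may come from the shared controls. The trend over dose was called in 3778 probe sets, 1680 upward and 2098 downward. The steepest slopes per 100 µM were those of scl-13 at 3.55 ± 0.05, scl-12 at 3.29 ± 0.03, scl-11 at 3.09 ± 0.04 and T26C12.2 at 2.94 ± 0.06. In the other direction stood lys-10, with the steepest slope of these 8 genes (adjusted p = 1e-22), F01D5.3 at -3.36 ± 0.11, W03F9.4 at -2.97 ± 0.06 and clec-190 at -2.70 ± 0.06. A linear slope does not show an even change with dose. scl-13, scl-12 and scl-11 had most of their rise already at 50 µM, and lys-10 stood at 0.40, -6.49 and -6.92 at 50, 100 and 200 µM. Of the sperm genes 52 of 62 had an upward slope and 0 a downward one, also adjusted over the list alone (adjusted p = 3.6e-43, and adjusted p = 0.094 with an estimated correlation). The mean of this list was 1.51, 1.5 and 2.04 above the control at 50, 100 and 200 µM, so most of its rise was also present at 50 µM.

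At 100 µM tannic acid, few genes changed by much, and those that did mostly rose. srlf-3 rose from 4.13 ± 0.50 to 8.72 ± 0.04 (SD, n = 3), by 4.59 ± 0.17 (adjusted p = 2e-13, and 6.1e-06 with the tannic acid arrays fitted alone). idpp-1 rose by 4.42 ± 0.25 (adjusted p = 3.9e-10, alone 1.8e-05), the transthyretin-like gene ttr-27 by 2.29 ± 0.16 (alone 0.00053) and nlp-26, a neuropeptide-like gene, by 2.26 ± 0.17 (alone 0.0014). irg-5, a gene of the response to infection, fell by 1.01 ± 0.11 (adjusted p = 7.6e-06, alone 0.0064), and T22B7.7 fell by 0.94 ± 0.13 (alone 0.013). A probe set of the yolk gene vit-4 lay at -1.48 ± 0.39 (adjusted p = 0.019, alone 0.098), so its call was lost in the fit alone.

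Sperm genes stood above the control at 100 µM tannic acid as well. Of 62 members 50 rose and 1 fell, or 55 and 3 adjusted over the list alone, with a median of 0.77 (adjusted p = 4.1e-31, and adjusted p = 0.2 with an estimated correlation). Fitted alone, 25 rose and 0 fell, ssp-31 among them at 1.53 ± 0.23 (alone 0.029). The mean of the list spread from -0.29 to 0.29 on the control arrays and from 0.51 to 0.87 on the treated ones. The oocyte list lay lower, with 3 of 23 called lower and 0 higher, or 6 and 0 adjusted over the list alone (median -0.36; adjusted p = 7e-06, and adjusted p = 0.57 with an estimated correlation). In limma on the tannic acid arrays alone 0 were called, with 4 lower at an unadjusted p under 0.05. Its mean spread from -0.22 to 0.16 on the control arrays and from -0.55 to -0.18 on the treated ones.

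Other groups moved less at this dose. Of the collagens 12 rose and 1 fell, also adjusted over the list alone, and 6 and 0 in the fit alone, with col-149 at 1.23 ± 0.16 and col-147 at 0.83 ± 0.09 (adjusted p = 0.011, and adjusted p = 0.58 with an estimated correlation). Of 28 muscle genes 7 rose and 0 fell, or 10 and 0 adjusted over the list alone, and 1 in the fit alone, the troponin gene tnc-2 at 1.10 ± 0.16 (adjusted p = 0.00083, and adjusted p = 0.2 with an estimated correlation). Of the lysozymes and antimicrobial peptides 14 rose and 1 fell, or 15 and 2 adjusted over the list alone, and 5 and 0 in the fit alone, among them lys-4 at 0.88 ± 0.11 (adjusted p = 0.0077, and adjusted p = 0.5 with an estimated correlation). Of the C-type lectins 15 were higher and 1 lower, or 18 and 1 adjusted over the list alone, and 5 and 0 in the fit alone, with clec-79 at 1.27 ± 0.17 (adjusted p = 0.034, and adjusted p = 0.33 with an estimated correlation). Their median of 0.07 became 0.00 under median centring.

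In total 1205 probe sets were higher and 542 lower at 100 µM tannic acid, against 289 and 34 with the tannic acid arrays fitted alone, 320 of them shared. Under median centring the split was 981 higher and 1187 lower, so the excess of rises depended on the scaling. In simulated data with 200 changed probe sets, 40.2% of the calls were false with all arrays and 8% with the tannic acid arrays alone. The count was 723 without replicate 3 of the controls, 1051 without replicate 2, 3122 without replicate 1, and 768 without replicate 2 of the treated group.

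At 200 µM tannic acid, largely the same genes led and several infection response genes fell. srlf-3 rose by 4.91 ± 0.17 (adjusted p = 5.4e-14, alone 2.3e-06), idpp-1 by 4.74 ± 0.25, W03G1.5 by 3.30 ± 0.31 and F14F8.8 by 3.19 ± 0.18 (2.87 with values under log2 4 raised to 4). The aspartyl protease gene asp-8 rose from 3.59 ± 0.18 to 6.66 ± 0.35 (SD, n = 3), by 3.07 ± 0.20 (adjusted p = 3.3e-09, alone 0.00016; 2.66 with values under log2 4 raised to 4), and cpr-4, a cathepsin B-like protease, by 2.10 ± 0.15 (alone 0.00052). irg-5 fell by 1.73 ± 0.11 (adjusted p = 1.7e-09, alone 0.00016), irg-4 by 1.49 ± 0.17 (alone 0.0026) and sysm-1 by 1.46 ± 0.15 (alone 0.0015). These 3 genes belong to the list of p38 targets, of which 6 of 17 rose and 4 fell, or 2 and 4 in the fit alone (adjusted p = 0.93).

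Muscle genes and sperm genes were higher as lists at 200 µM tannic acid. Of the muscle genes 11 of 28 rose and 0 fell, or 14 and 0 adjusted over the list alone, and 3 in the fit alone (median 0.26; adjusted p = 5.6e-08, and 0.01 with an estimated correlation). tnt-4, a troponin T, rose by 0.64 ± 0.10 (alone 0.024) and myo-1, a myosin of the pharynx, by 0.73 ± 0.12 (alone 0.027). Of the sperm genes 43 rose and 0 fell, or 55 and 0 adjusted over the list alone, and 19 in the fit alone (median 0.66; adjusted p = 1.4e-30, and adjusted p = 0.14 with an estimated correlation). Their mean on the treated arrays was 0.45 to 0.81, against -0.29 to 0.29 on the controls. Activated targets of DAF-16 were lower in 3 of 15 cases and higher in 0, or 5 and 0 adjusted over the list alone, and 2 in the fit alone, dod-3 at -1.09 ± 0.14 and lys-7 at -1.02 ± 0.15 (adjusted p = 0.007, and 0.038 with an estimated correlation). In the oocyte list 1 of 23 fell, cpg-3 at -0.42 ± 0.13, and 0 adjusted over the list alone, and limma on the tannic acid arrays alone called 0, with 1 lower at an unadjusted p under 0.05 (median -0.25; adjusted p = 0.018, and adjusted p = 0.65 with an estimated correlation).

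In total 973 probe sets were higher and 351 lower at 200 µM tannic acid, against 271 and 45 with the tannic acid arrays fitted alone, 314 of them shared. Under median centring the split was 789 and 617. In simulated data with 200 changed probe sets, 39.6% of the calls were false with all arrays and 4% with the tannic acid arrays alone. The count fell to 603 without replicate 2 of the treated group and to 691 without replicate 3 of the controls.

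At 300 µM tannic acid, oocyte, germline and yolk genes fell while genes of sperm, cuticle, muscle and intestine rose. With an estimated correlation, however, camera called 0 lists at this dose. srlf-3 was again highest, at 5.20 ± 0.17 (adjusted p = 1.2e-14, alone 7.1e-07), followed by Y38H6A.1 at 4.38 ± 0.12 and F14F8.8 at 4.35 ± 0.18. ora-1 rose by 4.27 ± 0.33 and W08E12.2 by 4.35 ± 0.56, the last with a spread of 2.03 (SD, n = 3) between the treated arrays. With values under log2 4 raised to 4, Y38H6A.1 rose by 3.02, F14F8.8 by 4.02 and W08E12.2 by 3.26. The caveolin gene cav-1 fell by 3.26 ± 0.60 (adjusted p = 0.00015, alone 0.012), sea-1 by 2.98 ± 0.25, pzf-1 by 2.62 ± 0.39 while the innexin gene inx-2 fell by 2.56 ± 0.22. With low values raised cav-1, sea-1 and pzf-1 changed by -2.42, -2.18 and -1.92. vit-4 fell by 3.20 ± 0.39 on 1 probe set and by 0.68 ± 0.09 on another, and mrp-4 by 2.47 ± 0.24 and 1.32 ± 0.18.

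All 23 oocyte and eggshell genes fell at 300 µM tannic acid, also adjusted over the list alone, and 22 in the fit alone (median -1.04; adjusted p = 1.8e-09, and adjusted p = 0.32 with an estimated correlation). lin-41 fell by 1.59 ± 0.27, nos-2 by 1.41 ± 0.19, and the oocyte maturation genes oma-1 and oma-2 by 1.30 ± 0.18 and 1.27 ± 0.22. The mean of the list ran from -1.33 to -0.61 on the 3 arrays, against -0.22 to 0.16 on the controls. Of 26 genes of germline proliferation and meiosis 19 fell and 0 rose, or 19 and 1 adjusted over the list alone, and 17 fell in the fit alone. Examples were glp-1, the Notch receptor of the germline, at -1.18 ± 0.17 and cye-1, cyclin E, at -1.43 ± 0.28, or -1.02 with low values raised (adjusted p = 0.00012, and adjusted p = 0.37 with an estimated correlation). All 5 vitellogenins fell, also adjusted over the list alone and in the fit alone (median -0.68; adjusted p = 0.0024, and adjusted p = 0.31 with an estimated correlation). Of the sperm genes 58 rose and 3 fell, also adjusted over the list alone and in the fit alone (median 1.31; adjusted p = 6.2e-22, and adjusted p = 0.31 with an estimated correlation).

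**Figure D3:**
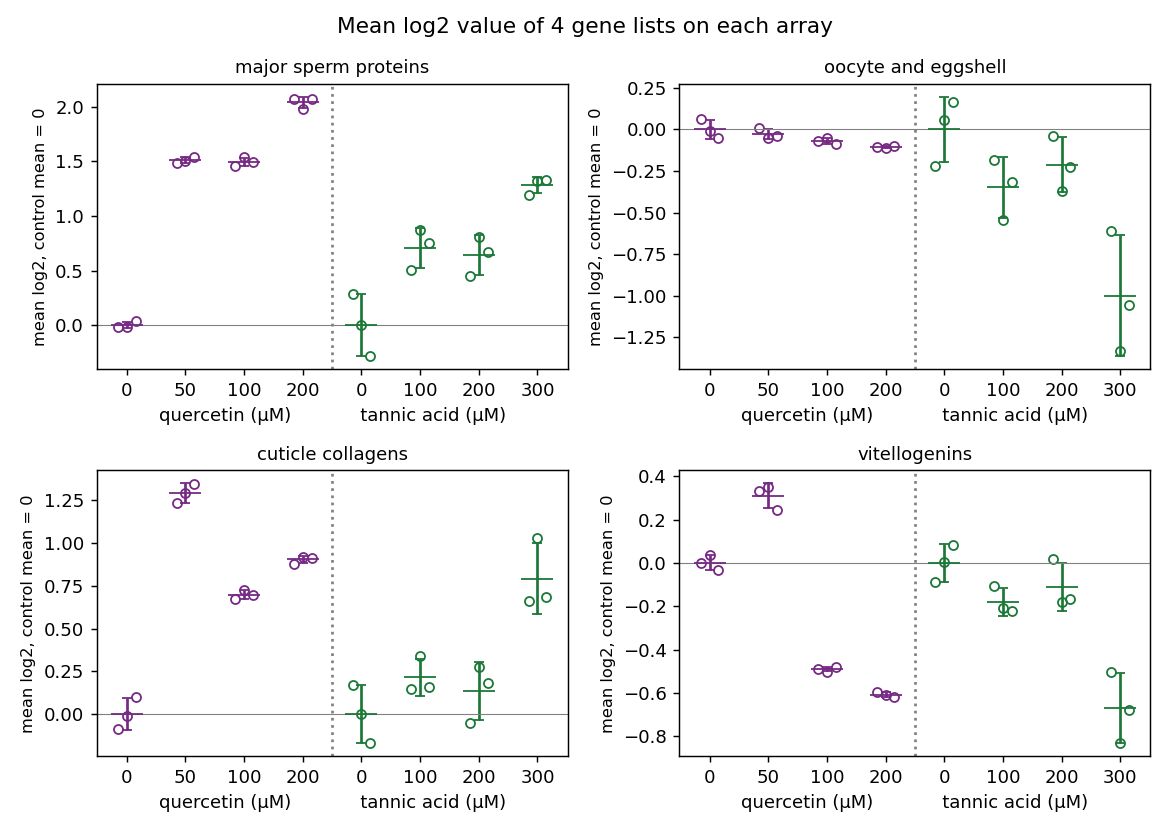
Mean log2 value of the sperm, oocyte, collagen and vitellogenin lists on each array (points), relative to the mean of the controls of the same compound, with the mean and SD of the 3 arrays per group, against the dose in µM. On the 3 arrays at 300 µM tannic acid the oocyte list lay between -1.33 and -0.61, and the mean of the sperm list was 1.28.

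Genes of somatic groups had higher values at 300 µM tannic acid. Whole animals were measured and the arrays were normalized to each other, so these rises are relative to other transcripts. A change per cell was not measured. Of 121 collagens 65 rose and 13 fell, or 66 and 13 adjusted over the list alone, and 60 and 11 in the fit alone, with col-120 at 3.21 ± 0.36 (adjusted p = 1.5e-06, and adjusted p = 0.31 with an estimated correlation). Of the muscle genes 21 rose and 1 fell, or 22 and 1 adjusted over the list alone, and 18 and 0 in the fit alone, with tnc-2 at 1.59 ± 0.16 (adjusted p = 3.7e-05, and adjusted p = 0.087 with an estimated correlation). Of 19 intestinal markers 11 rose and 2 fell, or 12 and 2 adjusted over the list alone, and 11 and 2 in the fit alone. They included ifb-2, an intermediate filament gene, at 1.35 ± 0.10 and the peptide transporter gene pept-1 at 1.18 ± 0.14 (adjusted p = 0.016, and adjusted p = 0.32 with an estimated correlation). Of 48 neuropeptide genes 24 rose and 1 fell, also adjusted over the list alone, and 19 and 1 in the fit alone (adjusted p = 0.00018, and adjusted p = 0.31 with an estimated correlation).

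Lists of antimicrobial, glutathione S-transferase and proteasome genes also moved at 300 µM tannic acid. Of 59 lysozymes and antimicrobial peptides 29 rose and 2 fell, or 30 and 2 adjusted over the list alone, and 23 and 2 in the fit alone, with nlp-26 at 3.33 ± 0.17 and cnc-2 at 2.40 ± 0.25, or 1.61 with low values raised (adjusted p = 0.00042, and adjusted p = 0.31 with an estimated correlation). Of 33 glutathione S-transferases 13 rose and 1 fell, also adjusted over the list alone, and 12 and 1 in the fit alone, gst-38 by 1.90 ± 0.15 (adjusted p = 0.015, and adjusted p = 0.38 with an estimated correlation). Of 33 proteasome genes 17 fell and 1 rose, also adjusted over the list alone, and 14 and 1 in the fit alone, with rpn-2 at -0.73 ± 0.12 (adjusted p = 0.0043, and adjusted p = 0.38 with an estimated correlation). The insulin signalling kinase genes pdk-1 and age-1 fell by 1.26 ± 0.12 and 0.86 ± 0.13, while their list of 13 had 6 lower and 1 higher (adjusted p = 0.059).

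In total 3326 probe sets were higher and 4219 lower at 300 µM tannic acid, which is 52.1% of those tested. The tannic acid arrays fitted alone gave 2659 and 3372, with 5983 shared. In simulated data with 200 changed probe sets the false shares were 36.4% and 8%. Far more probe sets were called here, so these shares do not carry over to the real calls.

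Across the tannic acid doses, 737 probe sets were called higher and 184 lower at all doses, and 210 and 18 with the tannic acid arrays alone. Independent lists would share 19 and 3.8 with all arrays and 0.99 and 0.025 with the tannic acid arrays alone. The simulations of unchanged groups with the same controls gave at most 0 and 0 in 20 draws, which cannot measure what the shared controls add. Part of the excess may come from the shared controls. Treated arrays of the same number correlated above 0.1 in 8 of 9 pairs between doses, which the simulations leave out. The genes with the largest mean change included srlf-3, idpp-1, F14F8.8, W03G1.5, ZK742.3, ora-1, asp-8 and nlp-26. All 8 were higher at each dose in the fit of the tannic acid arrays alone too, with ora-1 at 0.043 the highest of their adjusted p at 100 µM. A trend over dose was called in 7114 probe sets, 3152 upward and 3962 downward, and in 5343 with the tannic acid arrays alone. The slopes per 100 µM were 1.59 ± 0.05 for srlf-3, 1.47 ± 0.04 for Y38H6A.1 (1.02 with low values raised), -0.97 ± 0.12 for vit-4 and -0.97 ± 0.19 for cav-1. Of the oocyte genes 22 of 23 had a downward slope and 0 an upward one, also adjusted over the list alone (adjusted p = 4.5e-09, and adjusted p = 0.34 with an estimated correlation). The mean of this list was -0.35, -0.21 and -1 at 100, 200 and 300 µM, so its fall was not even over the doses.

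The compounds were tested in separate experiments, each with its own controls, and their responses were compared at the doses they share, 100 and 200 µM. The arrays of the experiments lie on different scales, with SDs of 3.69 to 3.76 for quercetin and 2.73 to 2.78 for tannic acid. The size of a log2 change may therefore not be comparable between them. Compound and experiment also cannot be told apart, so a difference in response may come from either. The fatty acid desaturase gene fat-5 differed by -6.39 ± 0.37 at 200 µM (tannic acid minus quercetin; adjusted p = 8.4e-11), with 5.49 under quercetin and -0.90 under tannic acid. F01D5.3 differed by 5.41 ± 0.33 (adjusted p = 1.9e-10), with -5.60 and -0.19. scl-13 rose by 8.63 under quercetin and lay at 1.98 with and without tannic acid, so it did not rise above log2 4 there, and with values under 4 raised to 4 its difference was -7.70. lys-10 fell by 6.92 under quercetin but lay at 2.18 in the tannic acid controls, where a fall could not be seen, so its difference of 6.87 rests on the quercetin change alone. In all, 1317 probe sets had the higher response under tannic acid and 953 under quercetin at 200 µM, and 955 and 697 did so at 100 µM. Of these 2270 and 1652, 989 and 596 had both tannic acid groups under log2 4, and 1246 and 1006 had a group above it in each experiment (572 and 674, and 520 and 486). Under median centring the splits of all calls were 1005 and 1305 at 200 µM and 688 and 1124 at 100 µM. The 95% interval of a difference had a median width of 0.40 to each side at both doses.

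Several gene lists responded differently at 200 µM. The sperm list rose by fewer log2 units under tannic acid, with 45 of 62 differences below 0 and 1 above, or 47 and 1 adjusted over the list alone. The counts of 45 and 1 were the same among the 54 with a group above log2 4 in each experiment. The median was -1.60 (camera adjusted p = 2.1e-34, and adjusted p = 0.096 with an estimated correlation). In all quercetin groups 8 of the 62 lay under log2 4, and in all tannic acid groups 0. With the different scales, a smaller log2 change need not be a smaller response. Of the 15 activated targets of DAF-16 6 had a difference below 0 and 0 above (4 and 0 of the 11 above log2 4 in each experiment), or 6 and 1 adjusted over the list alone (median -0.38; adjusted p = 2.6e-05, and 0.0043 with an estimated correlation). Of the collagens 43 differences lay below 0 and 10 above (24 and 6 of the 83 above log2 4 in each experiment), or 46 and 12 adjusted over the list alone (adjusted p = 1e-07, and adjusted p = 0.24 with an estimated correlation). Muscle genes had 10 of 28 differences above 0 and 0 below, or 12 and 0 adjusted over the list alone (median 0.31; adjusted p = 0.00017, and adjusted p = 0.075 with an estimated correlation).

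Other genes rose under both compounds at 200 µM. idpp-1 rose by 3.42 under quercetin and 4.74 under tannic acid, a difference of 1.32 with a 95% interval of 0.59 to 2.04 (adjusted p = 0.011). srlf-3 rose by 2.18 and 4.91, a difference of 2.73 (2.24 to 3.22). For W03G1.5, at 3.86 and 3.30, the difference of -0.56 did not pass the test and its interval ran from -1.48 to 0.35 (adjusted p = 0.45). For asp-8, at 2.37 and 3.07, it was 0.69 with an interval of 0.10 to 1.29 (adjusted p = 0.11). C31H1.5, at 4.46 and 0.91, and C34D4.3, at 3.99 and 1.32, rose by fewer log2 units under tannic acid. In all 436 probe sets were higher under both and 73 lower, against 99.9 and 49.8 for independent lists, and 105 were opposite, against 174. With each experiment fitted alone these were 173 against 41.7, 16 against 9.8 and 33 against 65.7. At 100 µM the counts were 361 against 81.9, 38 against 46 and 88 against 139.1, and with each experiment alone 162 against 30.9, 8 against 4.9 and 31 against 45.4. Sperm genes made up 41 of the joint rises at 200 µM and 44 at 100 µM, counting 1 probe set per gene, or 19 and 25 with each experiment alone. Across probe sets, which are not independent replicates, the fold changes correlated with r = 0.38 and rho = 0.26 at 200 µM and with r = 0.28 and rho = 0.17 at 100 µM, and with r = 0.46 and 0.37 among those with a group above log2 4 in each experiment.

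**Figure D4:**
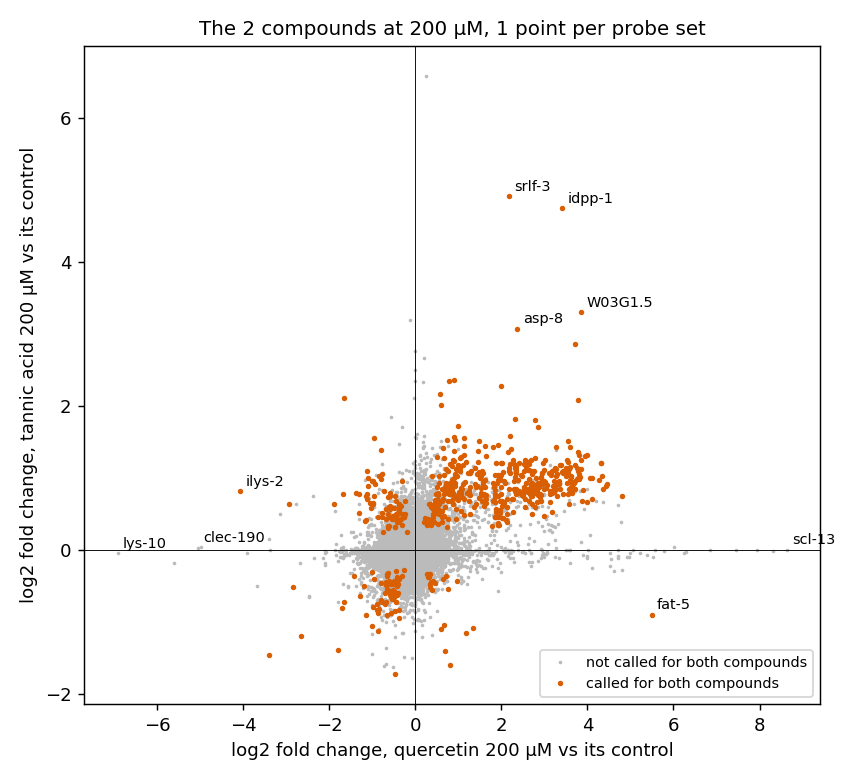
Log2 fold change at 200 µM quercetin (horizontal axis) against that at 200 µM tannic acid (vertical axis), 1 point per probe set, with probe sets called for both compounds in orange. scl-13 lies at 8.63 and 0.00 and lys-10 at -6.92 and -0.05, both with tannic acid arrays under log2 4, and srlf-3 at 2.18 and 4.91.

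The untreated controls of the experiments were compared to measure how far the experiments lie apart without treatment. Of the probe sets tested 1020 were higher and 13103 lower in the tannic acid controls, with a median difference of -2.30. With median centring the split was 8138 and 4282, and with quantile normalization of all arrays 6079 and 5684. The groups thus still differed in many probe sets after the arrays had been brought to a common scale. Experiment and control group cannot be told apart, so no gene was named from this comparison.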

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

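The tests of dauer markers and of background correction in this part were chosen only after the results were seen, while the splits of the arrays were planned. The results listed here are those in which the response to tannic acid minus the response to quercetin at the same dose passed limma's test of that difference. In 8 of the 10 genes named at 100 µM and in 7 of 10 at 200 µM both tannic acid groups lay under log2 4, where a rise above 4 is measurable and a fall is not.

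At 100 µM the test of the difference was passed by 1652 probe sets, 596 of them with both tannic acid groups under log2 4. The most positive differences were lys-10 at 6.49 (quercetin -6.49, tannic acid 0.00), the lipase gene fil-2 at 5.24 (-5.24 and 0.01), F01D5.3 at 5.17 (-4.90 and 0.28), W03F9.4 at 4.86 (-4.89 and -0.03) and ilys-2 at 4.59 (-3.80 and 0.79). Of these only F01D5.3 had a tannic acid control above log2 4 (8.28), so the others rest on the quercetin falls alone, and with values under 4 raised to 4 the tannic acid change of ilys-2 was 0.03 and the difference of fil-2 3.76. The most negative were scl-13 at -7.48 (7.46 and -0.02), scl-12 at -7.13 (7.10 and -0.04), C23G10.11 at -6.55 (6.51 and -0.04), scl-11 at -6.47 (6.45 and -0.03) and T26C12.2 at -5.98 (5.94 and -0.05), or -6.52, -7.10, -5.27, -6.18 and -5.10 with values under 4 raised to 4. Of 100 splits of the arrays 2 gave as many probe sets, the real one included, and the highest other count was 2594. The splits mixed treated and control arrays within each compound. Their share under 0.05 therefore concerns any response, and it cannot decide whether the compounds differ.

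At 200 µM the difference was passed by 2270 probe sets, 989 of them with both tannic acid groups under log2 4. lys-10 stood at 6.87 (quercetin -6.92, tannic acid -0.05), F01D5.3 at 5.41 (-5.60 and -0.19), the lectin gene clec-190 at 5.09 (-5.06 and 0.03), W03F9.4 at 5.04 (-4.99 and 0.04) and ilys-2 at 4.90 (-4.08 and 0.81, or 0.11 with values under 4 raised to 4). Again only F01D5.3 of these 5 had a tannic acid control above log2 4. In the other direction were scl-13 at -8.64 (8.63 and 0.00), scl-12 at -7.96 (7.95 and -0.01), scl-11 at -7.46 (7.46 and 0.00), T26C12.2 at -6.87 (6.86 and -0.01) and the desaturase gene fat-5 at -6.39 (5.49 and -0.90). With values under 4 raised to 4 the scl and T26C12.2 differences were -7.70, -7.95, -7.19 and -6.01, and fat-5, with a tannic acid control of 8.33, was unaffected. Here 3 of 100 splits gave as many, the real one included, and the highest other count was 3541. As at 100 µM, the share under 0.05 concerns any response and not a difference between the compounds. These 20 differences passed the test under each alternative run for them.

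For the rises of scl, grl, cuticlin and collagen genes under quercetin, weighed as 1 pattern, background correction of dim probe sets was examined. The 39 members at least 2-fold higher at 200 µM (3 scl, 5 grl, 2 cuticlin and 29 collagen genes) were chosen for that rise. Their median rise was 2.95, and also 2.95 with values under log2 4 raised to 4. Of these, 33 had controls at or above log2 4, with a median of 2.64, and 20 had controls at or above 6, with a median of 2.36. The 6 with controls under log2 4 had a median of 3.81 with low values raised. Raising low values hardly touches the 33, so the unchanged median cannot decide on background correction. The rise was, however, not confined to genes with dim controls. Dauer larvae among the treated animals may contribute, and this cannot be told apart. Of 11 dauer markers measured 6 were higher at 200 µM (cut-1 5.77, or 3.73 with values under 4 raised to 4, djr-1.2 2.95, or 1.96, col-2 4.55, hsp-12.6 2.23, tps-1 0.47 and also hil-1) and 2 lower (cut-5 -0.73 and cut-6 -1.18). The most abundant, lea-1 and icl-1, with control levels of 13.92 and 13.03, were not called (0.01 and -0.12), but such high baselines would hide a small share of dauers, and cut-1 and col-2 had been seen to rise before the list was written.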

How the results depend on the processing

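Raising low values to log2 4, leaving out 4 tannic acid arrays and running camera on each experiment alone were added after the data had been seen. No call of a named gene turned. Under a scaling alternative the medians of 3 called lists lost their sign (C-type lectins at 100 and 300 µM tannic acid, lysozymes and antimicrobial peptides at 50 µM quercetin, all to 0.00), and the excess of rises at 100 µM tannic acid was lost under median centring (69% and 45.2% of calls higher). The counts for 50, 100 and 200 µM quercetin became 3496, 3645 and 5373 with each experiment alone, and those for 100 and 200 µM tannic acid 323 and 316. That fit changes both the spread and the degrees of freedom, and the cause was not tested. With array weights they were 4039, 4920 and 5911 for quercetin, 4450 and 2845 for 100 and 200 µM tannic acid, 6406 for the quercetin trend, and 5024 and 4414 for the differences at 100 and 200 µM, and the cause was not tested. A minimum of 2-fold left 609, 659 and 1000 for quercetin, 289, 260 and 2084 for tannic acid, 973 and 1645 for the trends, and 670 and 923 for the differences, by its construction. The correlation of the compounds at 200 µM was 0.30 under quantile normalization and 0.34 with low values raised, and the cause was not tested. Of 62 list calls at single doses (39 up, 23 down), 7 (5 up, 2 down) held with an estimated correlation. For the same comparisons fry called 112 (71 up, 41 down). With an estimated correlation 0 lists were called for each trend and 1 for each difference. Without 1 array, the count for 100 µM tannic acid ran from 723 to 3122, that for 200 µM from 603 to 1887, and the correlation from 0.31 to 0.41, and the cause was not tested. The other counts stayed within 1.5 times. With the replicate number as a block the counts were 2243, 2279 and 3668 for quercetin and 1894, 1548 and 7708 for tannic acid, but not all arrays of a number deviated together (correlations of residuals from -0.42 to 0.38 for quercetin and from -0.56 to 0.69 for tannic acid). Among the treated tannic acid arrays 8 of 9 pairs of the same number correlated above 0.1 (0.04 to 0.69) and 7 of 9 arrays were closest to their own number, so these arrays may not be independent between doses. Without the 4 tannic acid arrays at 1 end of the within-group axis the tannic acid counts were 2330, 1519 and 7151. Calls of named genes held under all alternatives in 75, 82 and 107 cases at the quercetin doses and not in 29, 32 and 36, in 32, 41 and 146 at the tannic acid doses and not in 79, 60 and 18, and in all 36 for differences and trends.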

Other observations

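In this part all tests on stage, scaling and shared hybridisation and the list of male genes were chosen only after the results were seen, while the splits of the arrays were planned. The genes in the next paragraph were also chosen after their values were seen.

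Some genes responded to 50 µM quercetin in the direction opposite to that at the higher doses. The yolk gene vit-1 stood at 1.51, -1.61 and -1.68 at 50, 100 and 200 µM, and lys-10 at 0.40, -6.49 and -6.92. ptr-22, a gene of the patched-related family, fell at 50 µM (-1.26) and rose at 100 and 200 µM (1.65 and 1.24). The glucuronosyltransferase gene ugt-63 stood at -1.71 and 1.95 at 50 and 100 µM and was also higher at 200 µM. Between 50 and 100 µM, 63 probe sets were called higher and then lower and 51 lower and then higher, against 1143 in the same direction (128, 100 and 1755 with the quercetin arrays alone), and 107 of the 114 opposite ones were also opposite with values under log2 4 raised to 4. Between 100 and 200 µM these counts were 2, 2 and 1978 (4, 5 and 3238 alone), and between 100 and 200 µM tannic acid 0, 0 and 937, or 0, 0 and 229 with the tannic acid arrays alone.

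At 300 µM tannic acid oocyte and germline genes fell and sperm genes rose, though camera with an estimated correlation called 0 lists at this dose. Under quantile normalization of all arrays the oocyte median stayed at -1.04. The tannic acid arrays already had similar medians (3.72 to 3.95), so this cannot decide whether scaling plays a part. A harvest at an earlier stage stays open as a hypothesis: the 300 µM changes correlated with r = 0.61 with the main axis among the arrays within the 100 and 200 µM groups, which held 60.6% of their variance. The axis has no direction of its own and was turned so that oocyte genes fall on it. The sign of r was thus set by this choice, and only its size is informative. On that axis 58 of 62 sperm genes and 22 of 23 oocyte genes lay on opposite sides. Slower growth under tannic acid may give the same values as an earlier harvest, and the labels do not separate these.

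For the rise of sperm genes at all quercetin doses, hybridisation shared among gene copies is argued against as the whole cause, since the 20 sperm genes outside the msp family whose probe sets carry the plain suffix had a median of 1.39 at 200 µM (quartiles 0.39 and 3.18), with 15 called higher. An earlier stage at harvest may contribute and cannot be told apart, with r = 0.22 between the 200 µM changes and the tannic acid axis. The oocyte median was -0.10, with 0 of 23 called by limma (0 unadjusted) and 4 lower with the quercetin arrays alone. The mean of the vitellogenin list was 0.31, -0.49 and -0.61 at 50, 100 and 200 µM quercetin, and that of the germline list 0.02, 0.1 and 0.11. At 300 µM tannic acid these means were -0.67 and -0.53. Vitellogenins thus fell only at the higher quercetin doses, and the germline list did not fall. Of the 23 oocyte genes 19 lay above the top decile of the control arrays (log2 11.1), where a change may be compressed. In the tannic acid controls, on another scale, their median level was 11.2, and all 23 were still called lower at 300 µM. Of 15 listed male genes 2 were above log2 4 under quercetin (swm-1 and cwp-4) and 2 under tannic acid (swm-1 and snf-10), too few to weigh. limma called 0 of the former (0 unadjusted) and, at 300 µM tannic acid, snf-10 (0.92, or 0.75 with values under 4 raised to 4), which was not measurable under quercetin.

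The dauer list, with 11 of 14 genes above log2 4 in the quercetin experiment, had 5 higher and 1 lower at 50 µM quercetin and 5 and 2 at 100 µM. Under tannic acid only 5 of them were above log2 4, which leaves too few for a comparison. The residuals of the tannic acid arrays shared an axis that held 50.7% of the variance within groups. Its scores were 0.35 for control 1, 0.35 for 100 µM array 2, 0.30 for 200 µM array 2 and 0.44 for 300 µM array 2. At the other end were control 3 at -0.29 and array 1 at 100, 200 and 300 µM, at -0.25, -0.24 and -0.49. Arrays of the same number thus lay together at all treated doses but not in the controls.

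For single doses the arrays allow only 10 splits, too few for a share under 0.05. The real split gave the highest count in each case, as 1 of 10. The real and the highest other counts were 2176 and 3, 2214 and 1, and 3542 and 1 for 50, 100 and 200 µM quercetin. Under tannic acid they were, in order of dose, 1747 and 635, 1324 and 674, and 7545 and 3706. For the controls of the experiments they were 14123 and 0. For the trends 1 of 100 splits gave as many, the real one, with 3778 against 1737 for quercetin and 7114 against 6458 for tannic acid. This share under 0.05 sets chance aside only if the arrays are exchangeable. The splits mixed the arrays of all doses of a compound. The share therefore concerns any difference between the doses and cannot decide whether a response is graded. Samples of a group may be technical, and treated tannic acid arrays of the same number varied together, so chance between cultures was not excluded.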
